A study of Mus musculus with 8 samples.

How the data were processed

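Genomic DNA enriched for 5-hydroxymethylcytosine (5hmC, an oxidised form of 5-methylcytosine) by immunoprecipitation and sequenced (DIP-seq) was compared between sham-irradiated mice (0 Gy) and mice given 1 Gy of protons. Hippocampus and left ventricle of C57BL/6 mice were taken 20 weeks after exposure, and DNA of several mice was combined into each pool. Per the labels, 5 mice in each treatment group went into the pools and each condition has 2 pooled biological replicates. Whether each pool holds DNA of 5 mice or 5 mice were divided between both pools is not given in the sources used here, so a pool is the unit of replication throughout. Samples were grouped by tissue and dose from the sample titles into 4 groups of 2 pools, 8 libraries in all.

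The files deposited by the authors hold raw read counts per region of a merged peak list. The list has 21990 regions in hippocampus and 11664 in ventricle, and its coordinates are identical in the 4 libraries of a tissue. The submitters' processing notes name CASAVA 1.8.2, Bowtie 1.0.0, DESeq2 and the mouse genome build mm9, without saying what each was used for. The peak caller, its threshold, the rule by which peaks were merged, the handling of PCR duplicates and any input control are not given in the sources used here. Starts were raised by 1 because the files have the layout of BED intervals, so a start could be off by 1 if the authors counted from 1. These are counts over regions that had been chosen from enriched reads, so their sum is the depth in called regions and not the depth of the library.

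The totals were 266361 and 110699 counts in the sham pools of hippocampus, 1912037 and 1628905 in its irradiated pools, 81794 and 49649 in the sham pools of ventricle, and 86857 and 111035 in its irradiated pools. A count of 0 allows up to 3 counts, which is between 1.57 CPM (counts scaled to a common library total) in irradiated hippocampal pool 1 and 60.4 CPM in sham ventricular pool 2. Intervals for shares of counts are 95% exact binomial (Clopper-Pearson) intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

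Each tissue was tested with edgeR 4.0.16 (R 4.3.3) on the deposited counts. Libraries were scaled by TMM, low regions were removed by filterByExpr, and a quasi-likelihood F-test compared 1 Gy with 0 Gy at a Benjamini-Hochberg false discovery rate (FDR) of 0.05. CPM values of named regions are TMM-scaled and relate to the counts in the tested regions of the same fit, so they differ between fits. For regions paired between tissues these are the tested pairs only. The filter kept 21498 hippocampal and 2252 ventricular regions. The biological coefficient of variation was 0.602 in hippocampus and 1.44 in ventricle, and the median standard error of a log2 fold change was 0.95 and 2.38. Regions of one chromosome were tested as a set with camera (limma 3.58.1) at a preset correlation of 0.01, for chromosomes with at least 5 tested regions. Tissues were compared in regions that pair one to one with a reciprocal overlap of at least 50%, with a mean per group in the model, and the dose by tissue interaction was tested in the same model. The overlap of the region lists was compared with 1000 circular shifts of the ventricular regions within each chromosome. Shares of counts were compared by exact permutation tests, all two-sided. With 2 pools against 2, an exact permutation test cannot give a p below 0.333.

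The regions named in the text follow a rule fixed before the data were examined. For dose, they are regions past the FDR whose irradiated pools both lie above, or both below, both sham pools. Where fewer than 5 passed in a direction, the regions of that direction with the smallest p make up 5. For the interaction, the 3 smallest p are named where none passed. For tissues, regions past the FDR without overlap between tissues qualify. Chromosome X and each chromosome past the FDR are named. The group of high-count regions, defined as a mean CPM over 20 times that of the median region, was chosen after the data had been seen, as were the regions named only under an alternative setting.

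Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2-type size factors, total counts and loess offsets in edgeR, no filter on low counts, a filter of 20 counts in 2 libraries, an FDR of 0.1, each library left out, the replicate number as a block, other overlap rules, an offset for region width, an estimated correlation and fry for the chromosome sets. Alternatives added later were high-count regions left out, libraries thinned to the smallest total of the tissue, regions wider than 2544 bp only, tissue as the only term, further scalings of the chromosome sets, share correlations with tissue means removed, and other scalings of the floors of named regions.

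The scripts were tested on simulated data with the means and library sizes of the real pools, 50 regions changed at each fold size. At the fitted hippocampal dispersion, with 21667 regions tested, 0 of 50 regions changed 2-fold, 1 of 50 changed 4-fold, 4 of 50 changed 8-fold and 34 of 50 changed 32-fold were recovered. At the fitted ventricular dispersion, with 2061 regions tested, 0 of 50 were recovered at each of these sizes. At a dispersion of 0.02, 44 of 50 regions changed 8-fold were recovered in hippocampus and 32 of 50 in ventricle.

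Gene names are not given, because the files hold no genes and the gene table at hand is for another build than mm9. The lists of genes that had been fixed for testing in both tissues were therefore not analysed here, and regions are named by their mm9 position alone. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and region overlaps for the paired list with GenomicRanges 1.54.1.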

Results

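Hydroxymethylated DNA was profiled in hippocampus and left ventricle of C57BL/6 mice that had received 1 Gy of protons or a sham exposure (0 Gy) 20 weeks earlier. The question was whether a single exposure leaves a lasting change of 5hmC in brain and heart. Each of the 4 groups had 2 pools. Depth in regions differed between the tissues and, in hippocampus, followed the dose: the irradiated pools held 1912037 and 1628905 counts, the sham pools 266361 and 110699. The median region had 65 and 58 counts in the irradiated hippocampal pools and 12 and 3 in the sham pools. In ventricle the median region had 2 and 0 counts in the sham pools and 8 and 4 in the irradiated pools, and 54.7% of regions stood at 0 in sham pool 2.

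**Figure D1:**
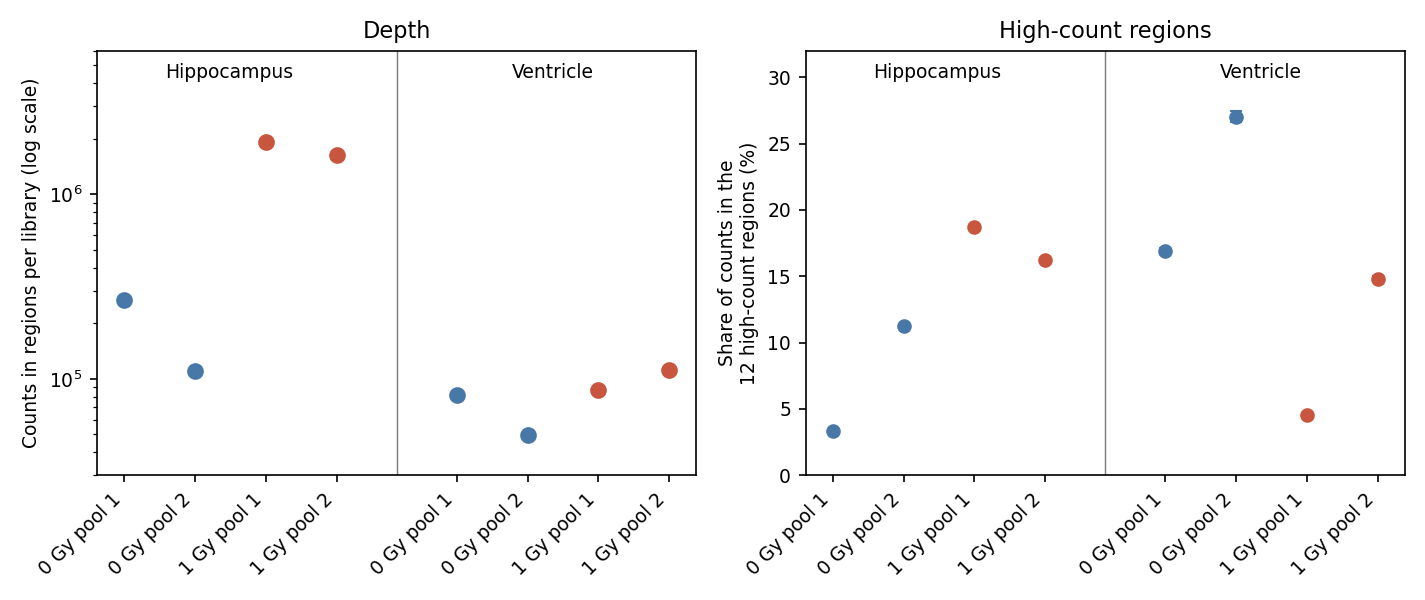
Left, total counts in regions per library on a log axis. Right, percent of a library's counts in the 12 high-count regions of its tissue, with 95% exact binomial intervals that are mostly narrower than the points. Blue points are sham pools and red points are irradiated pools. The irradiated hippocampal pools lie at 1912037 and 1628905 counts. Their high-count shares of 18.7% and 16.3% lie above those of both sham pools, and in ventricle the irradiated pools, at 4.52% and 14.8%, lie below both.

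The 21990 hippocampal regions covered 58.8 Mb and the 11664 ventricular regions 30.6 Mb. In hippocampus 78.3% of regions, and in ventricle 80.4%, were exactly 2544 bp wide. Between the first and last listed region, chromosome X carried 1.65 regions per Mb in hippocampus against a median of 9.27 over the 19 autosomes, 5.62 times fewer. In ventricle it carried 0.865 against 4.75, 5.49 times fewer. Among autosomes, chromosome 11 had the most regions per Mb in both tissues (11.7 and 6.08) and chromosome 3 the fewest (7.37 and 3.67). These densities describe 1 region list per tissue and have no replicate check.

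The counts of a tissue's regions did not rank alike in pools of the same group, except in irradiated hippocampus. Across hippocampal regions, which are not independent replicates, the Spearman correlation was 0.719 between the irradiated pools and -0.528 between the sham pools. Sham pool 2 correlated with the irradiated pools at 0.330 and 0.338, sham pool 1 at -0.330 and -0.336. In ventricle the correlation was 0.0480 between the sham pools and -0.466 between the irradiated pools. No pair was a repeat of 1 library, since the chi-square per degree of freedom was between 4.36 and 10.9 over the 12 pairs within tissues. In sham hippocampal pool 1 the number of regions went from 1287 at 11 counts to 2187 at 12 counts, and in irradiated ventricular pool 1 from 537 at 8 counts to 991 at 9 counts. In the other 6 libraries the largest such step was 1.31-fold. Of the 8 libraries these 2 pools also had the highest shares of counts on chromosome X (1.52% and 1.51%), the lowest on chromosome Y (0.124% and 0.210%) and the lowest in the high-count regions described below (3.34% and 4.52%), and each dose comparison includes 1 of them.

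**Figure D2:**
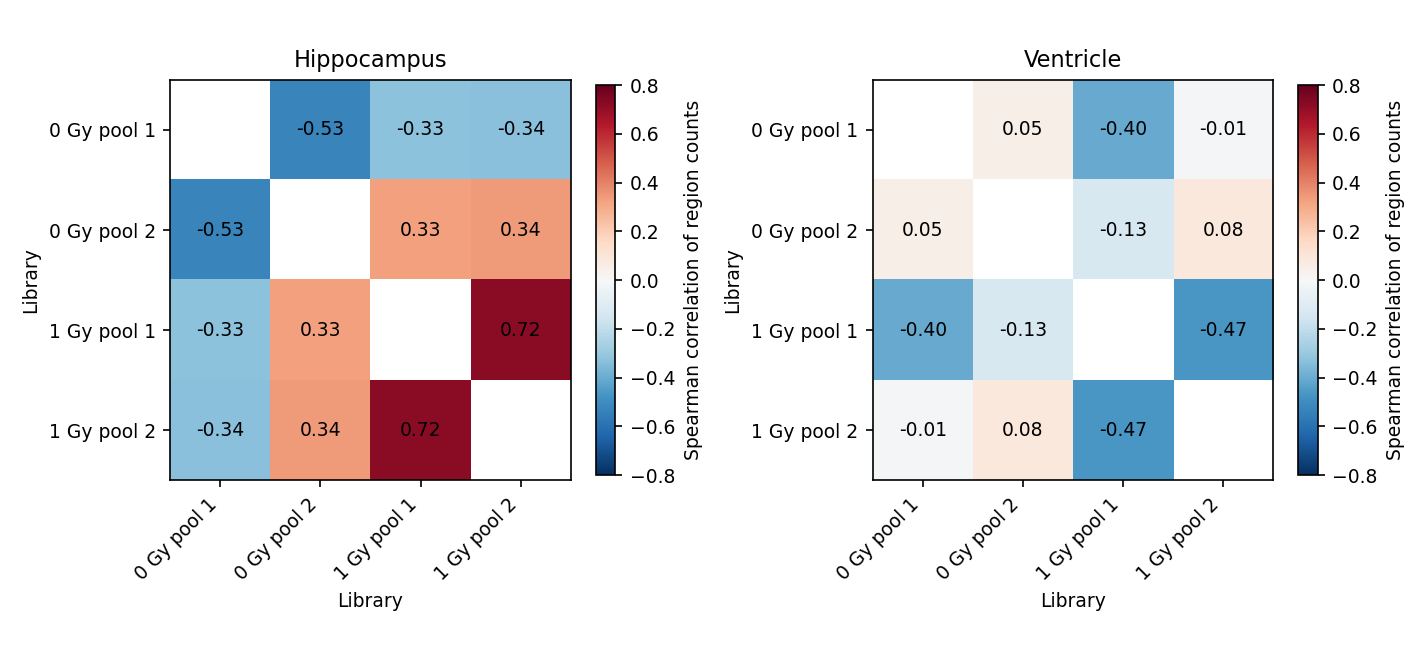
Spearman correlation of region counts between the libraries of hippocampus (left) and ventricle (right), from blue (negative) to red (positive). Only the irradiated hippocampal pools correlate above 0.4, and the irradiated ventricular pools correlate at -0.47.

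**Figure D3:**
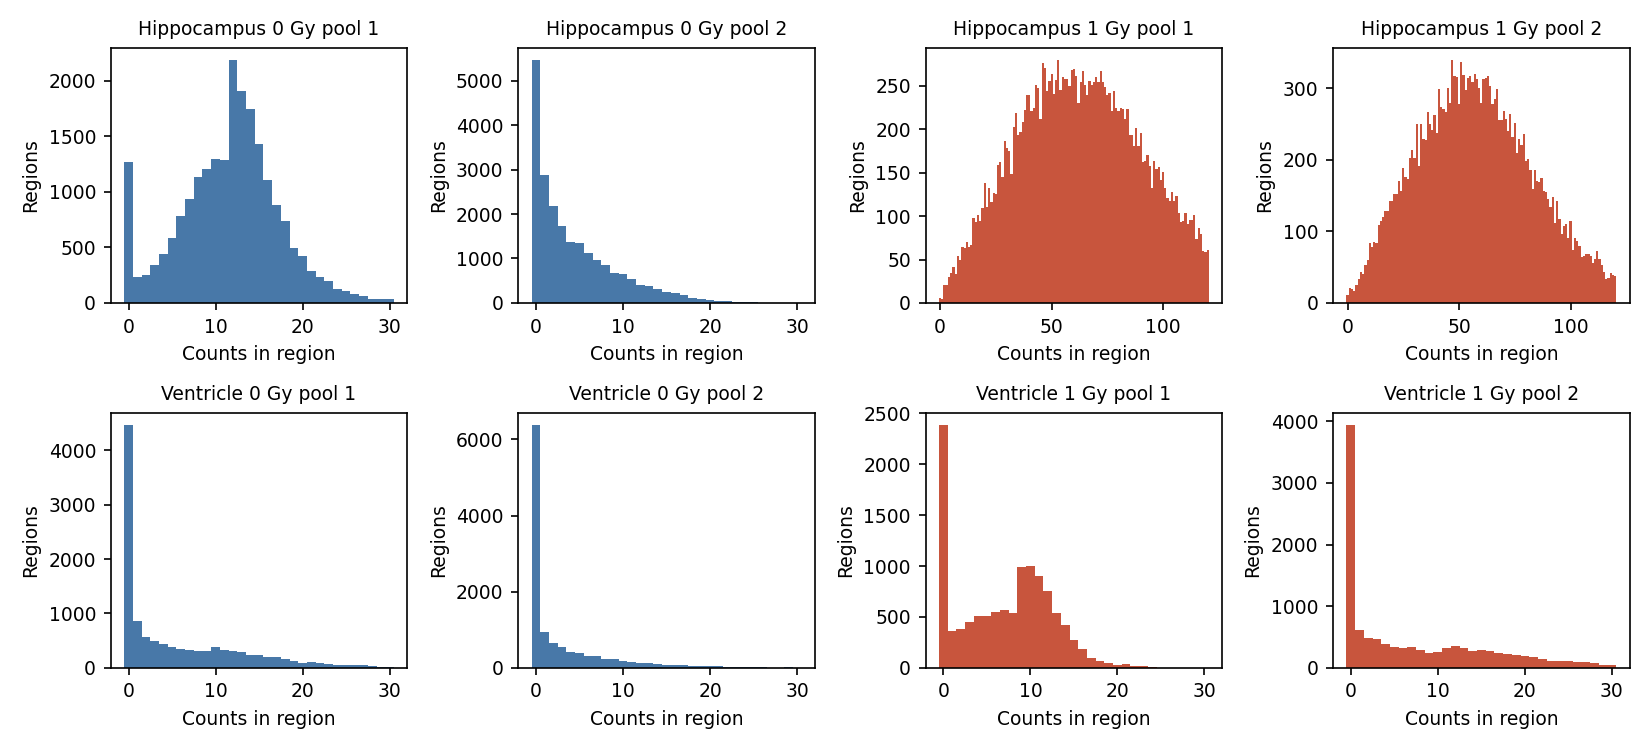
Number of regions (vertical axis) at each count (horizontal axis, cut at 30 or 120 counts) in the 8 libraries, blue for sham and red for irradiated pools. Sham hippocampal pool 1 steps up at 12 counts and irradiated ventricular pool 1 at 9 counts.

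In hippocampus no region passed the FDR for 1 Gy against 0 Gy. Of the 5 regions with the smallest p of a higher count, the one holding the most counts stood on chromosome 12 at 68158953 to 68161501, with 7 and 6 counts in the sham pools and 681 and 470 in the irradiated pools. That is 36.8 CPM ± 20.8 against 368 CPM ± 65.0 (SD, n = 2 pools each). Its log2 fold change in edgeR was 3.37 (SE 0.95, unadjusted p = 0.00775, FDR 1.00), 2.51 with loess offsets and 4.08 without sham pool 2. It passed when the libraries were thinned to equal totals (edgeR FDR 0.0121) and with either sham pool left out. In thinned libraries this region met the low-count filter only through the irradiated pools, in which it is high. That pass came from a single random draw and is no independent support. The 10 regions named here for hippocampus were chosen by p on these same pools. Passing with a sham pool left out is therefore no independent support, and it was not seen with an irradiated pool left out. The 4 others lay on chromosome 12 (100793583 to 100796325), chromosome 15 (18905435 to 18908889), chromosome 2 (168094780 to 168098990) and chromosome 7 (31367401 to 31370122). Both sham pools together held 1 or 2 counts there, and the irradiated pools 64 to 149 each. The fold on chromosome 12 at 100793583 was 17.7 with a counting interval of 4.85 to 147, and on chromosome 7 it was 29.3 with an interval of 5.19 to 1161. The log2 fold change on chromosome 7 was 4.67 in edgeR, 2.91 without sham pool 1 and 3.67 without irradiated pool 1. Without sham pool 2 that region, and without sham pool 1 the 3 others, stood at 0 in the remaining sham pool, so no size is given there.

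The hippocampal regions with the smallest p of a lower value lay on chromosome 8 (5134701 to 5137244), chromosome 12 (61451140 to 61453683), chromosome 18 (8856815 to 8859358), chromosome 3 (157609599 to 157612142) and chromosome Y (685094 to 687637). On chromosome 8 the value was 68.7 CPM ± 12.1 in sham pools and 7.07 CPM ± 0.313 in irradiated pools (SD, n = 2). Its log2 fold change in edgeR was -3.23 (SE 0.80, unadjusted p = 0.00382, the smallest in hippocampus, FDR 1.00), and -3.96 with loess offsets. Its counts were 19 and 9 against 12 and 10, so the difference rests on the deeper irradiated libraries holding about the same number of reads. The 4 other regions had log2 fold changes from -4.36 to -2.62, from -5.41 to -3.05 without sham pool 1 and from -2.49 to -2.07 without sham pool 2. Their sham against irradiated counts were 18 and 15 against 22 and 9 (chromosome 12), and 15 and 12 against 10 and 18 (chromosome 18). On chromosome 3 they were 17 and 11 against 23 and 13, so the same limit holds for these 3. On chromosome Y they were 5 and 18 against 3 and 8. The log2 fold change on chromosome Y was -4.36, and -10.06 with loess offsets.

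Over all 21498 tested hippocampal regions, edgeR gave 224 with an unadjusted p under 0.05, where 1074.9 would arise by chance. Both irradiated pools lay above both sham pools in 4858 regions and below them in 1818, and chance gives 33.3% of regions for both directions together. DESeq2 called 1 region, that on chromosome 8 (FDR 0.0207). Without sham pool 1 edgeR called 3363 regions (2201 higher, 1162 lower) and without sham pool 2 it called 4533 (3384 higher, 1149 lower), with 198 higher and 17 lower calls in both lists.

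**Figure D4:**
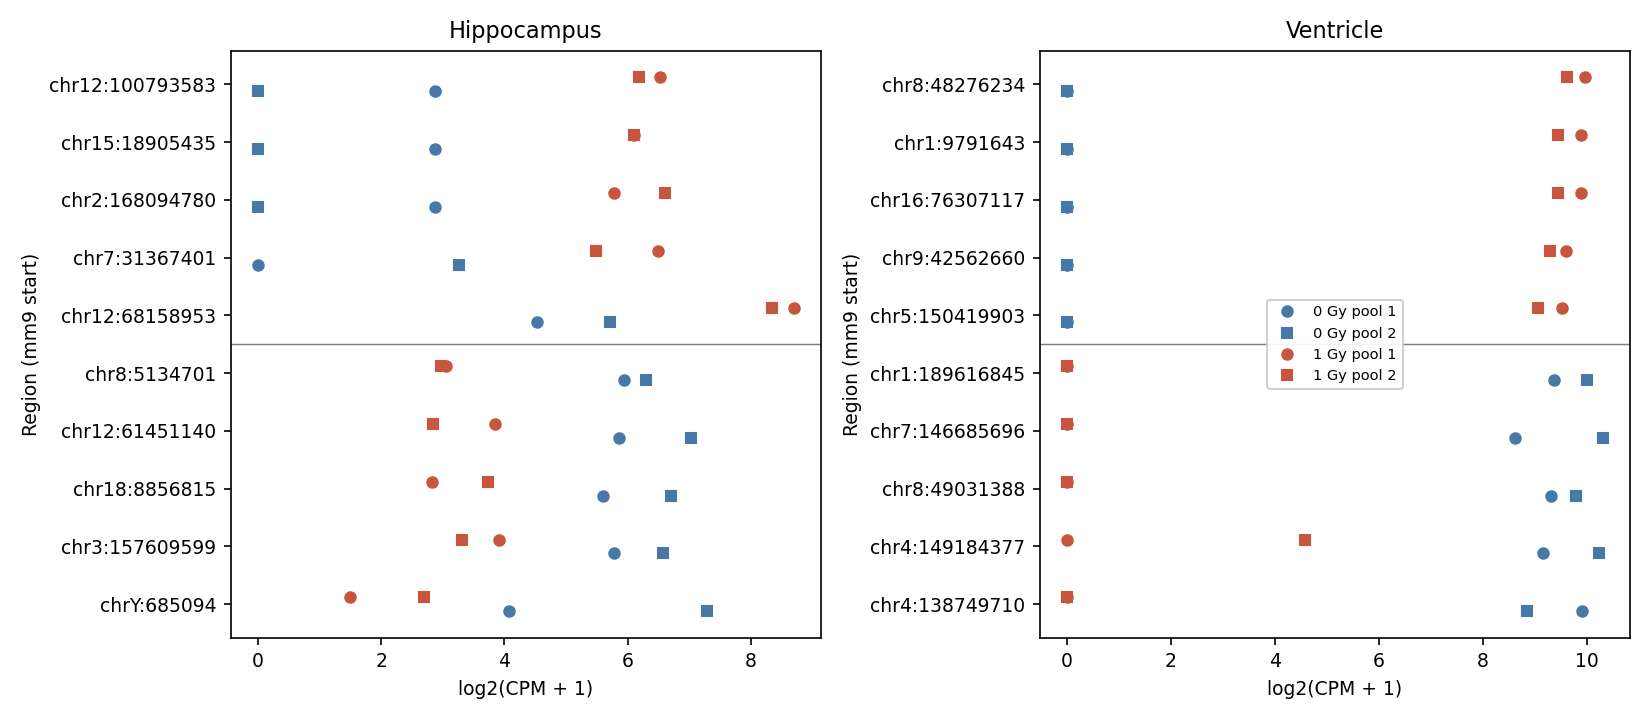
Level of each named region in the 4 libraries of its tissue, as log2 of TMM-scaled CPM plus 1, with regions named by chromosome and mm9 start. Blue marks sham and red irradiated pools, circles pool 1 and squares pool 2, regions above the line are higher and those under it lower after 1 Gy. None passed the FDR, and in ventricle the lower group of pools stands at 0 counts in 9 of 10 regions.

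Among hippocampal chromosomes, regions on X were lower and regions on Y higher after 1 Gy than other regions under camera at the preset correlation. Neither passed with an estimated correlation (adjusted p = 0.939 for X and 0.939 for Y). The 171 tested regions of X had a median log2 fold change 1.10 below that of other regions (difference -1.10, FDR 6.56e-13), and 37 of them lay lower and 11 higher in both irradiated pools than in both sham pools. The 14 regions of Y had a median 1.55 above that of other regions (FDR 0.00628), and 11 lay higher and 1 lower in both irradiated pools. With fry, which tests whether a set moves on balance in one direction, neither passed and the adjusted p of X was 0.524. Without sham pool 1 neither chromosome passed (Y difference 0.57, X difference 5.12). In that setting 159 of 267 X regions stood at 0 in the remaining sham pool, and with these at the 3-count floor the X difference was -1.30. That floor value takes unfiltered regions scaled by total counts, so it is not directly comparable with the edgeR differences. With all libraries the floor value was -1.49. Without sham pool 2 the X difference was -2.15. Loess offsets ended the call of Y (0.43), and in thinned libraries the X difference turned to 0.38. X took 1.52% of counts in sham pool 1 and 0.573% in sham pool 2, against 0.653% and 0.609% in the irradiated pools, so the share of sham pool 2 lay below both irradiated pools.

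In ventricle no region passed the FDR either. The regions with the smallest p of a higher count lay on chromosome 8 (48276234 to 48278813), chromosome 1 (9791643 to 9794186), chromosome 16 (76307117 to 76309660), chromosome 9 (42562660 to 42565203) and chromosome 5 (150419903 to 150423458). Both sham pools stood at 0 in these 5 regions, and the irradiated pools held 17 to 34 counts each. With the sham pools at the floor of 3 counts per library, the region on chromosome 8 was at least 9.08-fold higher and that on chromosome 5 at least 6.46-fold higher under TMM, and at least 5.88-fold and 4.15-fold higher when scaled by the total counts of all regions. The smallest unadjusted edgeR p was 0.00704. The regions on chromosomes 8, 1 and 16 passed when only the 128 regions that reached 20 counts in 2 libraries were tested (FDR 5.00e-04 to 7.81e-04). They met that filter only through the irradiated pools, in which they are high, so this pass is no independent support.

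The ventricular regions with the smallest p of a lower value lay on chromosome 1 (189616845 to 189620282), chromosome 7 (146685696 to 146688264), chromosome 8 (49031388 to 49033956) and chromosome 4 (149184377 to 149186920 and 138749710 to 138752253). The irradiated pools stood at 0 in 4 of them and the sham pools held 13 to 36 counts each. The region on chromosome 1 was at least 8.46-fold lower under TMM, 6.31-fold with DESeq2-type size factors and 13.9-fold with the total counts of all regions. That on chromosome 4 at 149184377, with 1 count in the irradiated pools, was 57.1-fold lower with a counting interval of 9.82 to 2298. Its log2 fold change in edgeR was -5.66, and -6.52 without sham pool 1, and without irradiated pool 2 it stood at 0 in the remaining irradiated pool. Of 2252 tested regions, 57 had an unadjusted p under 0.05 in edgeR, where 112.6 would arise by chance, and DESeq2 called 0. Both irradiated pools lay above both sham pools in 233 regions and below them in 411, against 33.3% by chance.

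No ventricular chromosome passed under camera. The 25 tested regions of X differed from other regions by -0.31 (FDR 0.837) and the 13 of Y by -0.83 (FDR 0.837). The adjusted p of X with an estimated correlation was 0.857. Chromosome Y passed, as lower after 1 Gy, without sham pool 1 and without irradiated pool 2.

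A small set of high-count regions took up to 27.0% of a library's counts, and its share was higher in irradiated than in sham pools of hippocampus and lower in those of ventricle. The 12 regions of each tissue include a pair on chromosome 2 near 98501468 and 98505767, a cluster of 5 on chromosome 9 from 2999461 to 3037379, and regions on chromosome 9 (35111504), chromosome 12 (3108505) and chromosome 5 (148421617), given here as hippocampal starts. In hippocampus the share was 3.34% and 11.2% in the sham pools and 18.7% and 16.3% in the irradiated pools, 7.28% ± 5.58 against 17.5% ± 1.73 (SD, n = 2). In ventricle it was 16.9% and 27.0% against 4.52% and 14.8%, a difference of -12.3 percentage points with SDs of 7.16 and 7.27 (n = 2). With 1 library left out the difference ranged from 6.25 (without sham pool 1) to 14.1 percentage points in hippocampus and from -17.5 to -7.17 (without irradiated pool 1) in ventricle. Each difference had an exact permutation p of 0.333, the smallest that 2 pools against 2 can give. In hippocampus 11 of the 12 lay higher in both irradiated pools, with a median log2 fold change of 1.57, and in ventricle 10 of 12 lay lower, with a median of -0.75. The 12 were chosen by their mean over these same pools, so the directions are no independent support. The ventricular regions on chromosome 2 at 123828440 (-2.70) and chromosome 8 at 73955513 (-2.39) owe most of their mean to sham pool 2. None of the high-count regions passed in edgeR. In thinned libraries 2 of the 12 in hippocampus did, on chromosome 2 at 98505767 (log2 fold change 0.87, edgeR FDR 3.14e-04) and chromosome 9 at 35111504 (1.25, FDR 3.02e-04), and with loess offsets the median was -0.34 in hippocampus, with 11 of 12 lower, and -0.13 in ventricle, with 7 lower and 5 higher.

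The region lists of the tissues overlapped more than shifted lists did. Of 21990 hippocampal regions, 1359 (6.18%) shared at least 1 bp with a ventricular region, against 554.6 ± 26.3 (SD) over 1000 circular shifts, a ratio of 2.45 (p = 0.000999 in a one-sided permutation test, the smallest that 1000 shifts can give). They met 1346 ventricular regions (11.5%). Among regions above the median CPM of their tissue the overlap was 650 of 10995, against 146.5 in shifted lists, a ratio of 4.44. The lists have no replicates, so this comparison carries no spread between animals.

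In the 733 regions paired between tissues, of which 600 were tested, none passed for hippocampus against ventricle in edgeR, and DESeq2 called 0. An unadjusted p under 0.05 was found for 30. In TMM-scaled CPM, each hippocampal library lay above each ventricular one in 2 regions, and in 0 the reverse held, where chance gives 2.86% for both directions. These 2, named after their values had been seen, were on chromosome 12 at 75904260 to 75906810 (3877 CPM ± 1702 against 1594 CPM ± 583, SD, n = 4) and on chromosome Y at 1264684 to 1268407 (1010 CPM ± 518 against 145.6 CPM ± 111.0). The ventricular region on chromosome Y is shorter (1264680 to 1267226) and held 1 and 2 counts in the sham and 2 and 8 in the irradiated pools. Their edgeR FDR was 0.843. With the replicate number as a block, 1 region passed, on chromosome Y at 2882868 to 2893084, where the ventricular region is shorter (2886932 to 2893076). Tissue shares of counts did not differ in exact tests of 4 libraries against 4: the high-count share was 12.4% ± 6.78 in hippocampus and 15.8% ± 9.23 in ventricle (exact permutation p = 0.571, adjusted over 3 shares 0.600).

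The dose effect was not shown to differ between the tissues in any of the 600 regions tested for an interaction. An unadjusted p under 0.05 was found for 53 regions in edgeR, 0 passed, and DESeq2 called 0. The smallest p values belonged to regions on chromosome 9 (41753788 to 41756331), chromosome 11 (88698126 to 88701350) and chromosome 4 (70037701 to 70040244). On chromosome 4 the counts were 50 and 49 in sham and 2062 and 1639 in irradiated hippocampal pools, and 69 and 33 in sham and 15 and 37 in irradiated ventricular pools. The difference of the dose effects there, hippocampus minus ventricle, was 2.71 on the log2 scale (SE 1.03, edgeR FDR 0.495), 2.00 with DESeq2-type size factors, 1.37 with total counts and 0.94 with loess offsets. The other 2 rest on ventricular sham pools at 0 counts, so no size is given for them. The region on chromosome 12 at 68158953, named above for hippocampus, held 23 and 10 counts in sham and 5 and 21 in irradiated ventricular pools, and its interaction did not pass (edgeR FDR 0.495).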

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

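The group of high-count regions, the tests of calls against single sham pools, the thinning to ventricular totals and the count of pairs with either stepped pool were chosen after the data had been seen. The other tests in this part were set down before their results were known.

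The share of counts in the 12 high-count regions was higher in both irradiated than in both sham pools of hippocampus and lower in those of ventricle, so the dose differences lay 22.5 percentage points apart (10.2 in hippocampus, -12.3 in ventricle). With 1 library left out the directions could not change, because the groups do not overlap. The sizes then ranged from 6.25 (without sham pool 1) to 14.1 in hippocampus. In ventricle they ranged from -17.5 to -7.17 (without irradiated pool 1), with -7.25 without sham pool 2. The pair on chromosome 2 near 98501468 and 98505767 alone gave a difference of 17.0 percentage points (7.91 against -9.06). Of the 36 ways to reassign dose within the tissues, 2 gave a difference as large in either direction, which is the fewest this design can give, so spread between pools and a dose effect cannot be told apart. An interaction at single regions is also open, since the smallest edgeR FDR over the 14 pairs with a region of high count in either tissue was 0.495 and the intervals of the interaction include a 2-fold difference. Reads of repeated sequence placed on few reference copies could account for such high counts, but this was not tested, as no mm9 sequence was at hand.

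The second pattern is the negative correlation between pools of 1 group, -0.528 for sham hippocampus and -0.466 for irradiated ventricle. Low depth alone was tested by thinning the irradiated hippocampal pools, which correlate at 0.719. They still correlated at 0.378 when thinned to 110699 counts, the smallest hippocampal total, and at 0.245 when thinned to 49649, the smallest ventricular one. Loss of counts on a fixed region list therefore weakened their correlation without removing it. Thinning cannot turn a positive correlation negative or repeat the region calling at low depth, so this test cannot decide on the negative values. A candidate explanation is a region list united from calls in single libraries, which would favour regions high in 1 pool and low in the other. Within regions at or above the count at which a pool's distribution stepped up, the correlations were -0.0290 in hippocampus and -0.110 in ventricle. The second lies just under the -0.1 that had been set. Keeping only regions where a pool is high narrows its range, which by itself weakens a correlation, so this test cannot decide. A united list cannot be told apart from other causes. A profile shared by sham hippocampal pool 1 and irradiated ventricular pool 1, the pools with the count steps, was tested by their correlation over paired regions (0.207). Of the other 15 pairs of libraries 9 exceeded it, more than the 4 set beforehand as evidence against it, but that bound was wrong, since the 9 are pairs without either pool, and the 6 pairs with 1 of them reached at most 0.107. The explanation stays open, and whether these pools were less enriched or mislabelled was not tested.

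The third pattern is the 3363 and 4533 hippocampal calls made when sham pool 1 or 2 is left out. The fold changes against each sham pool alone correlated at -0.331 across 21841 regions, with a covariance of -2.78. Calls in opposite directions numbered 568 where independent lists would share 281.7, a ratio of 2.02, while 198 regions were called higher and 17 lower in both, against 341.0 and 53.7. Both comparisons use the same irradiated pools, and 10 simulated draws without a dose effect gave a mean correlation of 0.108 and a covariance of 0.456. All simulated pools were given the same dispersion, so the draws cannot show how many calls arise without a dose effect. The simulated sham pools were independent, whereas the real ones correlated at -0.528, and that alone pushes the fold changes against them apart. The negative values and the excess of opposite calls over independent lists therefore restate the disagreement of the sham pools. A dose effect common to both sham pools and calls that follow the single sham pool that remains cannot be told apart by them. In both fits the spread between pools was estimated from the irradiated pools alone, which correlated at 0.719. The disagreement of the sham pools therefore did not enter that estimate, so the number of calls is no measure of a dose effect.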

How the results depend on the processing

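Thinned libraries, tissue as the only term, high-count regions left out and the added scalings of the chromosome sets were chosen after seeing the data. The planned gene lists were not run, as no mm9 annotation was at hand. Calls for dose in hippocampus went from 0 to 4 in thinned libraries, where 504 regions were tested (higher on chromosome 12 at 68158953, chromosome 2 at 98505767 and chromosome 9 at 35111504, lower on chromosome 2 at 116798985), to 1 with DESeq2, and ranged from 0 to 4533 with 1 library left out. In ventricle calls went from 0 to 3 with at least 20 counts in 2 libraries, and were 0 with each library left out. A lone pool was assumed to vary like the other group. The chromosome calls of hippocampus went from 2 to 0 with an estimated correlation and with fry, to 1 (X) with loess offsets, to 1 (Y) in thinned libraries, and ranged from 0 to 2 with 1 library left out. Those of ventricle ranged from 0 to 1. The hippocampal X difference of -1.10 turned to 0.38 in thinned libraries and 5.12 without sham pool 1, within a range of -2.15 to 5.12 with 1 library left out. Without sham pool 1, 159 of 267 X regions stood at 0 in the sham pool that remained. With these at the 3-count floor the difference was -1.30 (-1.49 with all libraries), so no direction can be given. The ventricular X difference of -0.31, which had not passed, turned to 0.18 in thinned libraries, 2.98 without sham pool 1 and 0.43 without irradiated pool 2, within a range of -0.37 to 2.98. Without sham pool 1, 90 of 140 X regions stood at 0 in the remaining sham pool, and with these at the floor the difference was 0.06 (0.07 with all libraries), so no direction can be given here either. In both tissues the floor values take unfiltered regions scaled by total counts, so they are not directly comparable with the edgeR differences. Tissue calls went from 0 to 7 with total counts only (1 higher in hippocampus, 6 lower), to 2 with loess offsets (chromosome Y at 2882868 higher, chromosome 2 at 98501468 lower), to 1 with the replicate block (chromosome Y at 2882868) and to 6 with tissue as the only term, where 98 were tested. The interaction gave 0 calls under all settings tried, and tissue and interaction gave 0 with each library left out. The replicate block changed no other call. Replicate numbers did not pair the pools (correlation of same-numbered deviations -0.00250 in hippocampus and -0.0596 in ventricle). The overlap was 759 at 50% of the region and 733 reciprocally, above 276.0 and 265.9 in shifted lists. The median log2 fold change of all hippocampal regions was 0.11 with TMM and -0.27 with total counts, and that of ventricle 0.20 and 0.42. Of the other single values, 213 kept direction and side of the threshold, 5 were newly past it and 5 no longer past it over settings with all libraries. With 1 library left out these were 99, 19 and 1. Depth limits the sham hippocampal and all ventricular pools, where the median region held 0 to 12 counts.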

Other observations

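The fit with tissue as the only term and the correlations of shares were chosen after the data had been seen.

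Hippocampal and ventricular libraries differed at 6 paired regions when dose was left out of the model and 98 regions were tested in edgeR. Higher in hippocampus were chromosome 2 at 98505767 to 98508310 (log2 fold change 0.66, SE 0.17, FDR 0.0308) and chromosome Y at 2882868 to 2893084 (1.44, SE 0.33, FDR 0.0161), where the ventricular region begins at 2886932 and is shorter. By total counts of all regions, that on chromosome 2 held 17476 and 63966 (sham), 108492 and 92252 (irradiated) CPM in hippocampus. In ventricle it held 84908 and 123849 (sham), 21299 and 75174 (irradiated) CPM, so the tissues overlapped and the direction is not settled. Higher in ventricle were chromosome 8 at 73955513 to 73958056 (-2.01, SE 0.55, FDR 0.0319), chromosome 10 at 37538756, chromosome 2 at 123828439 and chromosome 6 at 73468551. In these 4, sham ventricular pool 2 held 257, 94, 227 and 205 counts, and the other ventricular pools 11 to 53. Other groupings of the libraries were counted over the 35 splits of 4 against 4: only the real split gave as many as 6 calls, and the highest other split gave 5. Of the 16 splits that exchange 1 library between the tissues, 15 gave 0 calls and the other gave 5. In the model with a mean per group 0 regions passed, so the result is not carried over to the comparison averaged over doses.

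Few ventricular regions were filled in all 4 libraries. At least 5 counts were found in exactly 1 library in 39.1% of regions, in 2 libraries in 44.2%, in 3 in 14.4% and in all 4 in 2.22%, against 27.0% in all 4 in hippocampus. Irradiated pool 1 alone held 867 regions with at least 10 counts that stood at 0 in the 3 other pools. Irradiated pool 2 held 278 such regions, sham pool 1 held 197 and sham pool 2 held 8. In hippocampus there were 0 such regions in each pool, but the irradiated pools there stood at 0 in only 6 and 11 of 21990 regions. Both cutoffs are raw counts and depth differed between the tissues, so these values do not compare the tissues.

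Across the 8 libraries the share of counts in high-count regions went with the share on chromosome Y outside those regions (Pearson r = 0.871, exact permutation p = 0.00265, adjusted over 2 relations 0.00531; Spearman rho = 0.833, exact permutation p = 0.0154, adjusted 0.0308). The regions left out were those on the list of each tissue, and the ventricular list holds none on chromosome Y. The ventricular share therefore still includes the counterparts of the hippocampal high-count regions at 2855933 and 2882868, and is not free of such regions. Without the 2 libraries farthest from the median, r was 0.629. With the share on chromosome X, r was -0.416 (exact permutation p = 0.309) and rho -0.286 (exact permutation p = 0.501), and r was -0.672 without the 2 farthest libraries. With tissue means removed and the libraries permuted within tissues (576 arrangements), r for chromosome Y was 0.915 (exact permutation p = 0.00521, adjusted over 2 relations 0.0104), and with ranks within tissues it was 0.900 (exact permutation p = 0.0243, adjusted 0.0486). For chromosome X these were -0.625 (exact permutation p = 0.109) and -0.200 (exact permutation p = 0.733).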
